A study of Mus musculus with 6 samples.

How the data were processed

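The series holds RNA sequencing of 6 CT26 tumours from 6 BALB/c mice, 3 treated with PEGylated glutaminase and 3 with vehicle. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, tumour tissue was lysed, total RNA was extracted, messenger RNA was captured on poly-T beads and cDNA was primed with random hexamers. The p-values measure the spread between separate mice, 1 tumour each.

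The deposited table gives, for each gene model, the read count divided by a size factor of its library, an expression signal in normalized counts. The submitters' processing notes name FastQC, STAR, featureCounts, DESeq2 and DESeq, without versions or order. Aligner settings, genome build and strand setting are not given in the sources used here. Per the file headers, rows are BALB/cJ gene models joined to mouse gene symbols and Ensembl identifiers. The table has 40396 rows for 40303 gene models, since 93 rows repeat a model with another marker; each model was used once. 2902 gene models carry no symbol and hold 0.13% to 0.214% of reads. The same deposited table holds the authors' own comparison as mean signal, log2 fold change with its standard error, Wald score and p-values, raw and adjusted, per the file headers. In these the log2 fold change is positive where the PEG-glutaminase libraries are higher, checked against the library columns.

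Each library's values were whole multiples of the worth of 1 read within a tolerance of 0.01 for 100% of non-zero values, so whole reads were recovered. A separate check of the columns bore this out for 5 of 6 libraries. It did not judge PEG-glutaminase 2, whose step lies too near to 1, so for that library the recovery rests on the values alone. Because the deposited values are normalized, the main test was limma on log2(value + 1), with the count tests as alternatives. The plan named edgeR for raw counts and limma for normalized values. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. The 10 most abundant genes held 3.78% to 4.5% of reads. Size factors recomputed from the recovered reads of the 6 libraries ran from 0.965 to 1.04. No 2 libraries agreed within sampling noise (chi-square per degree of freedom at least 8.88).

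Genes with a mean of at least 10 normalized counts were tested with limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean trend and robust estimation), two-sided, with Benjamini-Hochberg adjustment over 13557 genes and a threshold of 0.05. An exact permutation test of 3 against 3 could not give a p below 0.1. In total 30 gene lists were fixed before the data were examined. The 28 with at least 5 tested genes were compared with all other genes by camera at an inter-gene correlation of 0.01, again with an estimated correlation, and by fry. List members overlap, so the lists are not independent. Genes were named by a rule fixed before the data were examined. It takes the 10 largest rises and falls among called genes with at least 1 CPM and no overlap between groups, leaving out pseudogenes, unnamed models and receptor segments, or, with fewer than 5 in a direction, the 5 of smallest p, said not to have passed. It adds up to 4 members of smallest p of each list that passed or held a called member, and genes from a fixed set whatever their result. The transcripts named under the other observations, and the ribosomal protein genes, were chosen after their values or those of related genes were seen.

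The test was tried on simulated counts for this comparison, with 13387 genes and 5 datasets of 200 changed genes. limma called 45.9% of genes changed 1.5-fold, 76.4% of those changed 2-fold and 89.2% of those changed 3-fold, and 7.31% of its calls were false. No simulated library stood apart across many genes, as vehicle 1 does in the skin list, so these shares may not hold for the tumours here. The simulated genes were independent, and 1 list passed over the 5 datasets. Independent genes cannot show how often the list test passes lists whose genes move together, so this count does not vouch for it.

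Alternatives planned before the data were examined were pseudocounts of 0.5 and 5, no filter, a mean of at least 50, at least 1 CPM in all libraries of a group with a mean of at least 50 reads, an adjusted p of 0.1, the replicate number as a block, edgeR 4.0.16 with 2 scalings, limma-voom, DESeq2 1.42.0, and each library left out in turn. Chosen after seeing the data were edgeR with TMM scaling, TMM and upper quartile scaling within the limma test, leaving out vehicle 1 and PEG-glutaminase 2 together, and a correction for transcript length, also without each library in turn. The correction subtracted, per library, a lowess curve (span 0.3) of the deviation from the gene's mean on log2 length. Lengths of the longest transcript came from GENCODE M21 through the table's Ensembl identifiers and covered 99.4% of tested genes. As that annotation is of another assembly than the gene models, it was used for lengths alone and no coordinates are given. Principal components used the 500 most variable genes, as log2 CPM with a prior count of 2. Tables were read with pandas 2.3.3 and scipy 1.17.1 in Python 3.11.15 and plots drawn with matplotlib 3.10.9.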

Results

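The data describe messenger RNA in tumours grown under the skin of BALB/c mice from CT26, a mouse colon carcinoma line of the same strain. 3 tumours came from mice injected into the peritoneum with PEGylated glutaminase, an enzyme that breaks glutamine down in the circulation, at 50 IU per kg. The other 3 came from mice given the vehicle, phosphate-buffered saline with 10% glycerol. Each mouse received 2 injections, given every 3 days, and each tumour gave 1 library. The recovered reads per library ran from 16455052 to 16791267 in the PEG-glutaminase group and from 17380129 to 18051480 in the vehicle group. Between 18300 and 19405 gene models had at least 1 read in a library. The most abundant transcript in every library was Vim, the intermediate filament protein of mesenchymal cells, at 0.529% to 0.79% of reads.

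The comparison asks which transcripts differ in tumours after PEG-glutaminase treatment. Glutamine levels are not among the data used here, so how far glutamine fell is not known. In the PEG-glutaminase tumours 1 of 13557 tested genes rose and 4 fell. Hbb-bs, a beta globin of red blood cells, rose 2.15-fold, from 427 ± 40 to 927 ± 150 normalized counts (SD, n = 3 per group). Thbs2, a secreted matrix protein that limits blood vessel growth, fell from 6462 ± 785 to 3131 ± 415, and Id3, an inhibitor of basic helix-loop-helix transcription factors, fell from 289 ± 23.9 to 132 ± 15.2. Mylip, a ubiquitin ligase that lowers the low-density lipoprotein receptor, fell from 722 ± 34.8 to 442 ± 10.9, and Rbm3, a cold-inducible RNA-binding protein, fell from 2794 ± 217 to 1795 ± 76.1.

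On the log2 scale the change of Hbb-bs was 1.11 ± 0.13 (SE; limma, adjusted p = 0.0371). Thbs2 changed by -1.05 ± 0.12, Id3 by -1.13 ± 0.14 and Mylip by -0.70 ± 0.09, each with a limma adjusted p of 0.0371. Rbm3 changed by -0.64 ± 0.08 with a limma adjusted p of 0.0454. Of these, 3 differed by at least 2-fold, 1 higher and 2 lower. The groups of 3 did not overlap in any of the 5. Their Ensembl identifiers in the table are ENSMUSG00000052305 for Hbb-bs, ENSMUSG00000023885 for Thbs2, ENSMUSG00000007872 for Id3, ENSMUSG00000038175 for Mylip and ENSMUSG00000031167 for Rbm3. Hbb-bs shares near-identical sequence with Hbb-bt, and Rbm3 with the pseudogene Rbm3-ps, and how reads common to both were counted is not given in the sources used here. Hbb-bt stood at 1.22 ± 0.21 and Rbm3-ps at -0.46 ± 0.08, neither past the limma threshold and both called by DESeq2.

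By the naming rule, the genes nearest to passing among those higher were Mmp9, a gelatinase of neutrophils and macrophages, Hbb-bt, P2rx3, an ATP-gated ion channel, and Tarbp1. Their log2 differences were 0.85 ± 0.13 for Mmp9, 1.33 ± 0.21 for P2rx3 and 0.70 ± 0.12 for Tarbp1 (limma adjusted p of 0.0954, 0.104 and 0.111). Itgbl1, next among those lower, stood at -0.60 ± 0.09 (limma adjusted p = 0.0757). Across all genes, 2498 had an unadjusted p under 0.05. The 2 groups did not overlap in 25.8% of genes, where chance gives 10%.

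The calls were lost without vehicle 1, vehicle 2 or PEG-glutaminase 1, where limma called 0 genes, with 2366, 1683 and 1936 at an unadjusted p under 0.05, while without vehicle 3, PEG-glutaminase 2 or PEG-glutaminase 3 it called 5, 20 and 26. Of the 5 genes, Hbb-bs and Thbs2 passed without vehicle 3, all passed without PEG-glutaminase 2, and all but Rbm3 passed without PEG-glutaminase 3. The count at 2-fold or more was 5 without vehicle 3, 8 without PEG-glutaminase 2, 15 without PEG-glutaminase 3 and 0 without any of the others. With the number as a replicate block limma called 1 gene, none of the 5. DESeq2 on the recovered reads called 483 genes, 220 higher and 263 lower, and edgeR called the same 5 as limma.

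**Figure D1:**
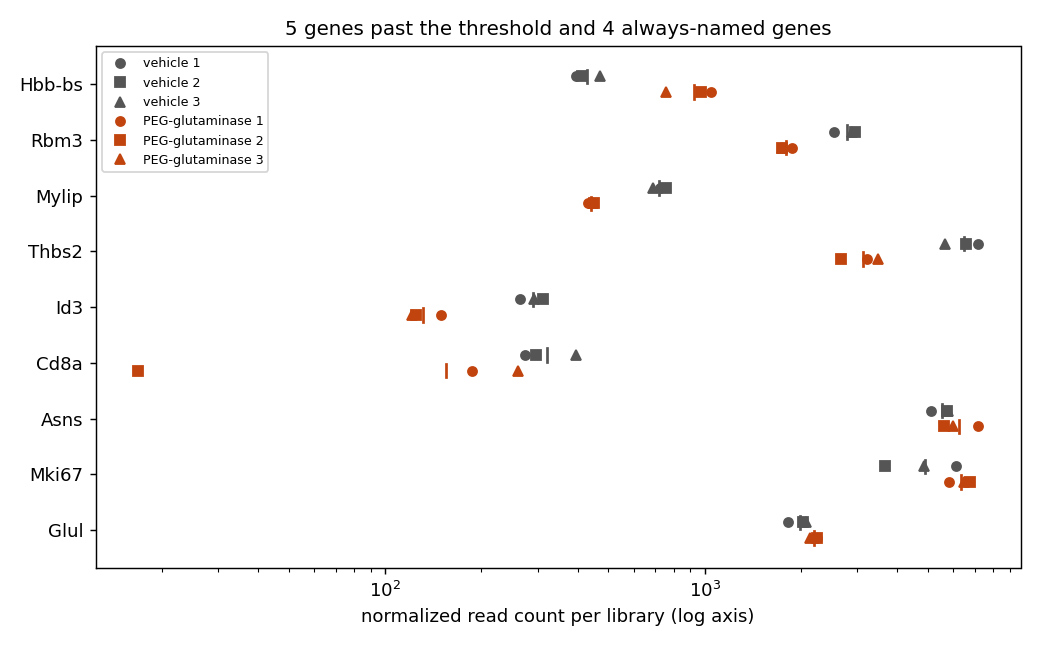
Normalized read counts (log axis) of the 5 genes past the threshold and of 4 genes named whatever their result, 1 point per library and a bar at each group mean (n = 3). Hbb-bs lay between 395 and 472 in vehicle tumours and between 759 and 1048 in PEG-glutaminase tumours, while Cd8a ranged from 17 to 260 across the PEG-glutaminase tumours.

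Gene groups fixed before the data were examined were tested with camera at a preset inter-gene correlation of 0.01. Of 28 testable lists, 17 passed, 6 higher and 11 lower. The other splits of the 6 libraries into equal groups passed 9 to 18 lists each, so passing at the preset correlation is weak evidence. With an estimated correlation camera passed 0 lists (lowest adjusted p = 0.371 with an estimated correlation, 1 list at an unadjusted p under 0.05). fry, which asks whether a list's genes move one way on balance, passed 1 list, that of glutamine metabolism. Counts of single members over all genes are by limma; edgeR called 0 members of every list except the erythroid one, and DESeq2, whose calls are given beside them, found members in 20 of the 28 lists.

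Genes of glutamine and glutamate metabolism and transport rose as a group, with a median log2 change of 0.15 over 30 genes, 25 of them higher (camera adjusted p = 0.000107; adjusted p = 0.371 with an estimated correlation). By limma 0 members passed over all genes (7 at an unadjusted p under 0.05), DESeq2 called 3 higher (Cad, Pfas and Slc1a5), and 4 rose by limma when adjusted over the list alone. Those 4 were Cad, which starts pyrimidine synthesis, at 0.74 ± 0.13, Pfas of purine synthesis at 0.47 ± 0.11, the glutaminase Gls2 at 0.70 ± 0.17 and the glutamine transporter Slc1a5 at 0.38 ± 0.10. Glul, glutamine synthetase, stood at 0.16 ± 0.08. Slc38a2, another glutamine carrier, stood at 0.09 ± 0.10 and the cystine carrier Slc7a11 at -0.02 ± 0.10; none of these 3 passed. Glul stood at 0.0979 without vehicle 1, and Slc38a2 at 0.16 without vehicle 1, 0.0365 without vehicle 3 and 0.14 without PEG-glutaminase 2. Leaving out 1 library put Slc7a11 at -0.0944 to 0.0855.

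De novo nucleotide synthesis genes rose by a median of 0.18, with 19 of 24 higher (camera adjusted p = 8.08e-05; adjusted p = 0.548 with an estimated correlation). By limma 0 members passed over all genes (13 unadjusted), DESeq2 called 5 higher and 1 lower, and by limma adjusted over the list alone 8 rose and 1 fell. Umps, which makes uridine monophosphate, stood at 0.43 ± 0.08 and Gart of purine synthesis at 0.43 ± 0.08. Cell cycle genes rose by a median of 0.23, with 33 of 35 higher (camera adjusted p = 1.72e-07; adjusted p = 0.548 with an estimated correlation). Over all genes limma called 0 members (13 unadjusted) and DESeq2 3, all higher, and by limma adjusted over the list alone 9 rose, among them the cyclin Ccne2 at 0.58 ± 0.11, the replication licensing factor Cdc6 at 0.60 ± 0.13 and the helicase subunit Mcm4 at 0.38 ± 0.11. Mki67, the Ki-67 antigen, stood at 0.40 ± 0.17, and at 0.21 without vehicle 2, and did not pass. PEG-glutaminase 2 had the highest mean of the cell cycle list, 0.30 above the mean of the 6 libraries, and without it the median was 0.11.

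The ATF4 amino acid response list, the genes that cells switch on when amino acids run short, rose by a median of 0.14, with 24 of 35 higher (camera adjusted p = 0.0133; adjusted p = 0.652 with an estimated correlation). Over all genes limma called 0 members (12 unadjusted); by limma adjusted over the list alone, and by DESeq2 over all genes, 2 rose and 1 fell, namely Aldh1l2, a mitochondrial folate enzyme, at 0.68 ± 0.14, the transcription factor Atf5 at 0.33 ± 0.09 and the stress protein Nupr1 at -0.48 ± 0.13. The central members did not pass in either. Asns, asparagine synthetase, stood at 0.17 ± 0.11, Chac1 at 0.17 ± 0.19, Trib3 at 0.05 ± 0.18 and Atf4 at -0.05 ± 0.10. Ddit3 stood at -0.62 ± 0.41 and Atf3 at -0.68 ± 0.42, while the serine synthesis enzymes Psat1 and Phgdh stood at 0.20 ± 0.08 and 0.27 ± 0.10. Ddit3 stood at -0.36 without vehicle 2, -0.93 without vehicle 3 and -0.31 without PEG-glutaminase 2, Atf3 at -0.18 without PEG-glutaminase 2 and Asns at 0.0681 without PEG-glutaminase 1. Leaving out 1 library put Chac1 at 0.0283 to 0.35, Trib3 at -0.0440 to 0.22 and Atf4 at -0.10 to 0.0400. The list did not pass without vehicle 1 (median 0.11), vehicle 3 (0.06), PEG-glutaminase 1 (0.07) or PEG-glutaminase 3 (0.09), and passed at 0.21 without PEG-glutaminase 2. That library had the lowest mean of the list, -0.20, under vehicle 1, 2 and 3 at -0.0835, 0.0625 and -0.0795. PEG-glutaminase 1 and 3 had means of 0.18 and 0.12.

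Cytosolic aminoacyl-tRNA synthetases rose by a median of 0.11, with 16 of 20 higher (camera adjusted p = 0.0222; adjusted p = 0.652 with an estimated correlation), and 0 members passed by limma over all genes (4 unadjusted) or adjusted over the list alone, or by DESeq2. Eprs and Iars, which charge glutamate, proline and isoleucine tRNAs, stood at 0.28 ± 0.09 and 0.27 ± 0.09. The unfolded protein response list of the endoplasmic reticulum rose by a median of 0.10, with 18 of 22 higher (camera adjusted p = 0.00561; adjusted p = 0.652 with an estimated correlation), and 0 members passed by limma over all genes (4 unadjusted) or adjusted over the list alone, or by DESeq2. Its chaperones Hyou1 and Pdia4 stood at 0.34 ± 0.11 and 0.27 ± 0.09. Neither list passed without vehicle 1 (medians 0.07 and 0.08) or without PEG-glutaminase 1 (0.04 and 0.05).

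Interferon response genes fell by a median of -0.82, and all 33 tested members were lower (camera adjusted p = 2.64e-16; adjusted p = 0.548 with an estimated correlation). In 27 of them the groups did not overlap, where the share over all tested genes was 25.8% and chance gives 10%. Over all genes limma called 0 (21 unadjusted) and DESeq2 called 13 lower, and by limma adjusted over the list alone 10 fell, among them the transcription factors Irf1 at -0.69 ± 0.17 and Irf9 at -0.59 ± 0.16, the chemokine Cxcl11 at -0.87 ± 0.24 and Ciita, which switches on MHC class II genes, at -1.17 ± 0.32. MHC class I presentation genes fell by a median of -0.66, with 13 of 13 lower (camera adjusted p = 3.11e-06; adjusted p = 0.548 with an estimated correlation). Among these B2m stood at -0.42 ± 0.15, the peptide transporter Tap1 at -0.66 ± 0.23 and the immunoproteasome subunit Psmb10 at -0.76 ± 0.25, and 0 passed by limma over all genes (5 unadjusted) or adjusted over the list alone. DESeq2 called 3 lower, Psmb10 and Tap1 among them. Without PEG-glutaminase 2 the values were -0.38 for Irf9, -0.25 for B2m, -0.41 for Tap1 and -0.48 for Psmb10.

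T and NK cell markers fell by a median of -1.17, with 27 of 28 lower (camera adjusted p = 4.08e-09; adjusted p = 0.548 with an estimated correlation), and 0 members passed by limma over all genes (6 unadjusted) or adjusted over the list alone, while DESeq2 called Cd3d and Icos lower. Cd3d of the T cell receptor complex stood at -1.85 ± 0.59, the costimulator Icos at -1.64 ± 0.53 and Ifng at -1.11 ± 0.33. Cd8a, the marker of cytotoxic T cells, stood at -1.74 ± 1.14, with 322 ± 64.7 normalized counts in vehicle tumours and 155 ± 125 in PEG-glutaminase tumours. Immune checkpoint genes fell by a median of -1.02, with 11 of 12 lower (camera adjusted p = 0.000578; adjusted p = 0.548 with an estimated correlation). By limma 0 passed over all genes (6 unadjusted) and 3 fell when adjusted over the list alone, the same 3 that DESeq2 called over all genes, Havcr2 (-1.12 ± 0.20), Lag3 (-1.55 ± 0.37) and Ctla4 (-1.72 ± 0.49). Pdcd1, which encodes PD-1, stood at -1.54 ± 1.11 and Cd274, its ligand, at -0.93 ± 0.39. Without PEG-glutaminase 2 the values were -0.40 for Pdcd1, -0.50 for Cd274, -0.52 for Cd8a, -1.13 for Cd3d and -0.996 for Icos; without PEG-glutaminase 3 Pdcd1 stood at -2.36. Tigit was the 1 member that was higher, at 0.35 ± 0.13.

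Dendritic cell markers fell by a median of -0.79, with 15 of 18 lower (camera adjusted p = 8.44e-06; adjusted p = 0.548 with an estimated correlation). Over all genes limma called 0 members (10 unadjusted) and DESeq2 called 4 lower, Itgax and H2-Aa among them; by limma adjusted over the list alone 7 fell, among them Itgax, which encodes CD11c, at -1.11 ± 0.20, Xcr1 of cross-presenting dendritic cells at -0.96 ± 0.22 and the MHC class II chain H2-Aa at -1.50 ± 0.38. PEG-glutaminase 2 had the lowest mean of the interferon (-1.02), MHC class I (-0.83), T and NK (-1.71), checkpoint (-1.20) and dendritic (-0.43) lists. Without it the medians were -0.47, -0.38, -0.61, -0.39 and -0.75 in the same order, each past the preset test. PEG-glutaminase 2 also had the highest means of the muscle (1.37), fibroblast (0.48) and endothelial (0.32) lists.

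Macrophage and monocyte markers did not pass, with a median of -0.07 and a mean of 0.03 over 24 genes and a test direction of lower (camera adjusted p = 0.95), and Cd68 stood at 0.14 ± 0.11. Neutrophil markers (median -0.01, adjusted p = 0.993, 12 genes) and B and plasma cell markers (median -0.09, adjusted p = 0.993, 6 genes) did not pass either. Fibroblast and matrix genes had a median of 0.05 (adjusted p = 0.599) and endothelial markers one of 0.18 (adjusted p = 0.0834). Epithelial markers had a median of -0.49 (adjusted p = 0.229) and skeletal muscle markers one of -0.30 (adjusted p = 0.296). Over all genes limma called 0 members of these 7 lists (1 to 5 unadjusted in each). DESeq2 called Mmp9, 1 endothelial and 1 macrophage marker higher, 1 macrophage and 1 epithelial marker lower, and 0 in the B cell, fibroblast and muscle lists. By limma adjusted over the list alone 1 neutrophil marker, Mmp9, rose and 2 epithelial markers fell, and 0 passed in the other 5. Skeletal muscle markers did pass without PEG-glutaminase 2 (median -1.03) and without vehicle 2 (-0.73), endothelial markers without PEG-glutaminase 3 (0.35) or with no filter (0.18), and neutrophil markers, as higher, without PEG-glutaminase 2 (0.26). The endothelial median was -0.00234 without PEG-glutaminase 2 and 0.0602 without vehicle 2, the epithelial one -0.27 without vehicle 1, and the muscle one -0.11 without PEG-glutaminase 1 and 0.0373 without PEG-glutaminase 3, none of them past the test. The macrophage list had a median of 0.0697 without vehicle 3, 0.0515 without PEG-glutaminase 2, -0.16 without vehicle 1 and -0.15 without PEG-glutaminase 1, and did not pass. Cd68 stood at 0.0853 without vehicle 2, 0.0727 without PEG-glutaminase 1 and 0.25 without PEG-glutaminase 3. Leaving out 1 library put the fibroblast median at -0.0461 to 0.23, the B cell median at -0.31 to 0.27 and the neutrophil median at -0.27 to 0.26.

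Keratinocyte and skin markers fell by a median of -3.31, with 15 of 15 lower (camera adjusted p = 7e-06; adjusted p = 0.548 with an estimated correlation), and 0 members passed by limma over all genes (2 unadjusted) or adjusted over the list alone, or by DESeq2. This group followed vehicle 1, where the list's mean lay 5.29 above the mean of the 6 libraries. Krt14, a keratin of basal skin cells, had 1727 normalized counts in vehicle 1, 0.981 and 56.9 in the other vehicle tumours and between 0 and 2.07 in the PEG-glutaminase tumours. Without vehicle 1 the median was -1.01, past the preset test. Lor, Krt77 and Dsc3 were listed at 0 in all 3 PEG-glutaminase libraries, and with these at a floor of 3 reads over the group the median with all libraries was -3.09. Trp63, a transcription factor of basal epithelium, stood at -2.02 ± 0.61.

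Adipocyte markers fell by a median of -0.32, with 9 of 10 lower (camera adjusted p = 0.00886; adjusted p = 0.548 with an estimated correlation). By limma 0 passed over all genes (4 unadjusted), DESeq2 called Plin4 lower, and by limma adjusted over the list alone 2 fell, the lipid droplet protein Plin4 (-1.02 ± 0.24) and the lipase Pnpla2 (-0.34 ± 0.09). The list did not pass without vehicle 1 (median -0.30) or PEG-glutaminase 3 (-0.26), and passed at -0.49 without vehicle 2. Of the erythroid list only 3 genes could be tested, under the minimum of 5 for a list test: Hbb-bs, Hbb-bt and Alas2, the first enzyme of haem synthesis in red cells, at 1.16 ± 0.32. By limma 1 of the 3 rose over all genes and 3 when adjusted over the list alone, and DESeq2 called Hbb-bs and Hbb-bt higher.

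**Figure D2:**
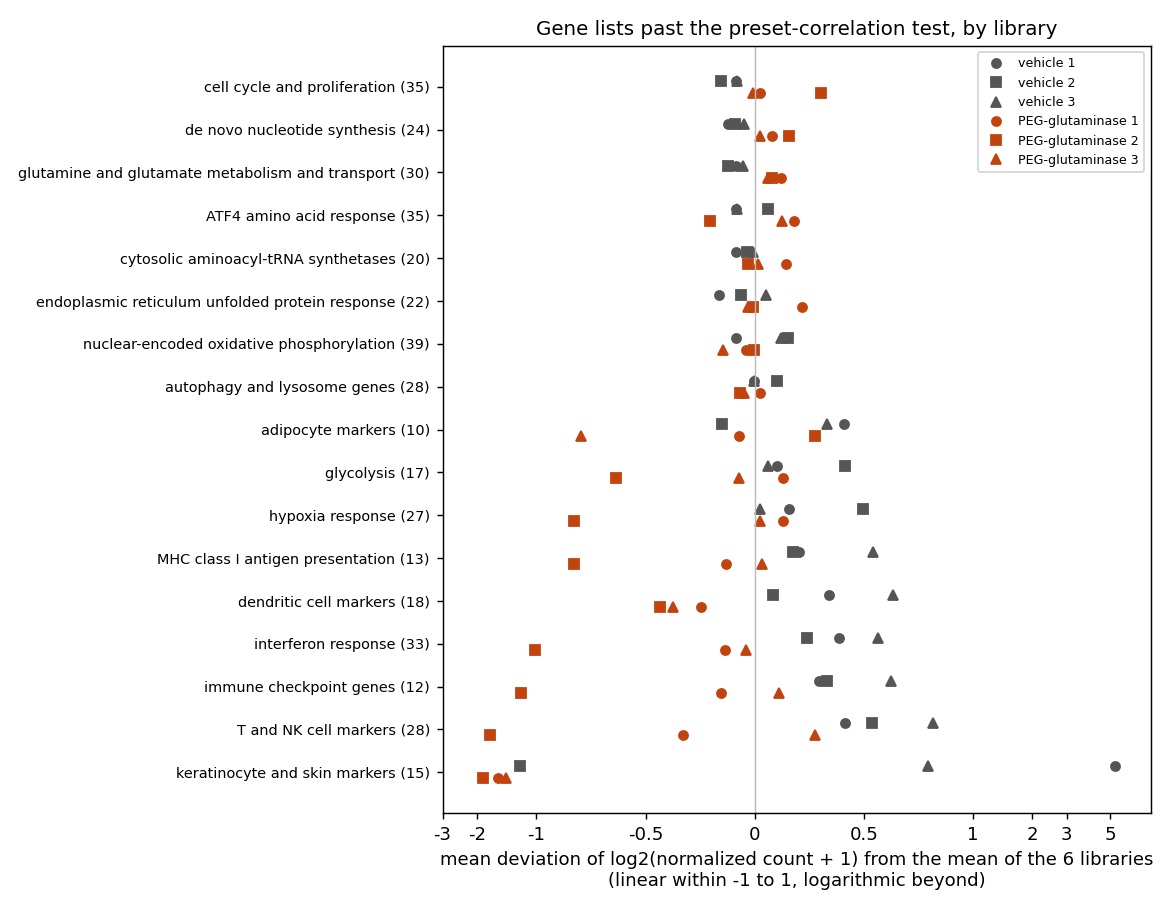
Mean deviation of each library from the mean of the 6 libraries, in log2(normalized count + 1), for the 17 lists that passed the preset-correlation test, with the number of tested genes in parentheses (axis linear from -1 to 1, logarithmic beyond). All 3 PEG-glutaminase libraries lay below all 3 vehicle libraries in the interferon, MHC class I, T and NK, checkpoint and dendritic lists, with PEG-glutaminase 2 lowest in each, and vehicle 1 lay at 5.29 in the skin list.

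Hypoxia response genes fell by a median of -0.39, with 25 of 27 lower (camera adjusted p = 0.000136; adjusted p = 0.632 with an estimated correlation), and glycolysis genes by -0.36, with 17 of 17 lower (camera adjusted p = 3.17e-05; adjusted p = 0.56 with an estimated correlation). In both lists 0 members passed by limma over all genes (2 and 4 unadjusted) or adjusted over the list alone, while DESeq2 called Pdk1 lower. The glucose transporter Slc2a3 stood at -0.99 ± 0.38 and Pdk1, a kinase that inhibits pyruvate dehydrogenase, at -0.66 ± 0.28. The glycolytic enzymes Pfkm and Pkm stood at -0.36 ± 0.10 and -0.37 ± 0.14. PEG-glutaminase 2 had the lowest means, -0.83 and -0.63, and without it the medians were -0.13 and -0.16, both past the preset test, with Slc2a3 at -0.53, Pdk1 at -0.39 and Pkm at -0.24. The other treated libraries overlapped the vehicle libraries, of which vehicle 2 was highest in both lists. Hypoxia means were 0.129 and 0.0241 in PEG-glutaminase 1 and 3, against 0.155, 0.498 and 0.0232 in vehicle 1, 2 and 3. Glycolysis means were 0.129 and -0.0738 against 0.101, 0.416 and 0.0627. Without PEG-glutaminase 3 the hypoxia median was -0.60.

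Nuclear-encoded oxidative phosphorylation genes fell by a median of -0.11, with 31 of 39 lower (camera adjusted p = 0.001; adjusted p = 0.674 with an estimated correlation). By limma 0 members passed over all genes (9 unadjusted), and 2 fell by limma adjusted over the list alone and by DESeq2, the cytochrome oxidase subunit Cox5b (-0.65 ± 0.14) and the complex I subunit Ndufa1 (-0.57 ± 0.13). The list did not pass without PEG-glutaminase 3 (median -0.06), nor after a correction for transcript length (-0.00114), and passed at -0.18 without vehicle 1 and -0.05 without vehicle 2. Autophagy and lysosome genes fell by a median of -0.15, with 18 of 28 lower (camera adjusted p = 0.038; adjusted p = 0.632 with an estimated correlation), and 0 passed by limma over all genes (5 unadjusted) or adjusted over the list alone, while DESeq2 called 1 higher. Tfeb, a regulator of lysosomal genes, stood at -0.34 ± 0.09 and the autophagosome protein Map1lc3b at -0.33 ± 0.11. This list did not pass without vehicle 2 (-0.08), PEG-glutaminase 2 (-0.10) or PEG-glutaminase 3 (-0.09), or after the length correction (-0.10), with the replicate block (-0.15) or with edgeR and TMM scaling (-0.14).

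The NRF2 and glutathione list (median -0.04, adjusted p = 0.25), cholesterol synthesis (0.02, adjusted p = 0.852) and the immediate early and heat shock genes (-0.09, adjusted p = 0.81) did not pass. The p53 targets had a median of 0.08 and a mean of -0.08, with a test direction of higher (adjusted p = 0.0834). Over all genes limma called 0 members of these 4 lists (1 to 7 unadjusted in each), and DESeq2 called 2 NRF2 list genes higher and 1 lower, 2 p53 targets and 2 immediate early or heat shock genes higher and 0 cholesterol genes. By limma adjusted over the list alone, 2 NRF2 list genes rose and 2 fell, 1 p53 target and 1 immediate early gene rose, and 0 cholesterol genes passed. The cholesterol list passed as higher without vehicle 3 (0.24) and as lower without vehicle 2 (-0.10), and the immediate early list as lower without PEG-glutaminase 1 (-0.20). The p53 list passed without vehicle 2 (0.10), with no filter (0.08), with edgeR under 3 scalings (0.08 to 0.09), with limma-voom (0.08) and after the length correction (0.12), and its median was 0.0501 without PEG-glutaminase 1 and 0.0470 without PEG-glutaminase 2, not past the test in either. Leaving out 1 library put the NRF2 list at -0.0810 to -0.0241 and the immediate early list at -0.20 to 0.0214. Of 13 mitochondrially encoded protein genes 0 could be tested.

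Fold changes followed transcript length. Across 11213 genes with a mean of at least 50 normalized counts, the log2 fold change had a Spearman correlation of 0.32 with the length of the longest annotated transcript, across genes, which are not independent replicates. The median was -0.18 in 551 genes with transcripts of up to 1000 nucleotides and 0.10 in 2595 genes with transcripts over 5000. The deviations of single libraries had correlations from -0.45 in vehicle 2 to 0.38 in PEG-glutaminase 3, with 0.20 in vehicle 1.

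**Figure D3:**
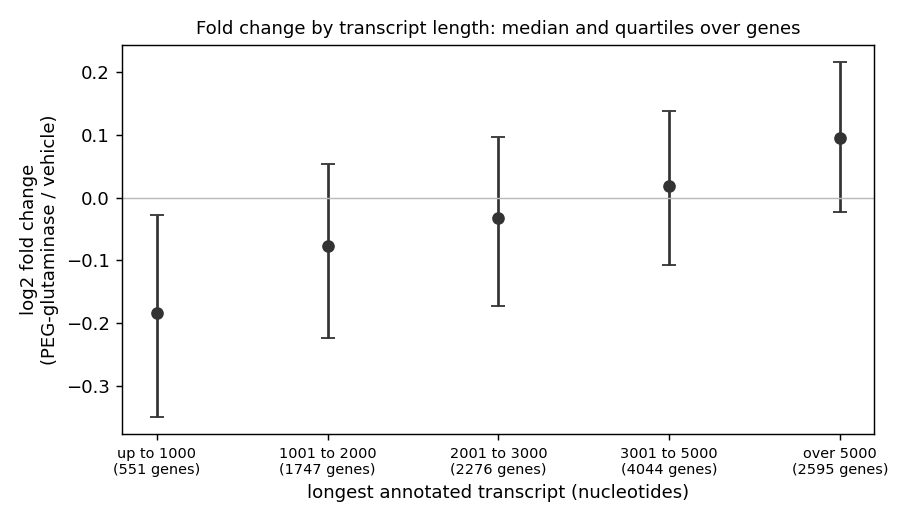
Log2 fold change (PEG-glutaminase over vehicle) by length of the longest annotated transcript in nucleotides; points are medians over genes and bars run from the lower to the upper quartile. Medians run from -0.18 in the shortest class to 0.10 in the longest.

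The authors' deposited table holds their own DESeq2 comparison, which called 447 genes at an adjusted p under 0.05, 225 higher and 222 lower with PEG-glutaminase. Across 13557 genes its log2 fold changes had a Spearman correlation of 0.906 with those computed here. The authors' deposited table and the limma test shared 3 calls in the same direction, and it shared 218 with DESeq2 on the recovered reads. The shared genes were Id3, Mylip and Rbm3, while Hbb-bs (log2 fold change 0.62, adjusted p = 0.32) and Thbs2 (-0.68, adjusted p = 0.164) were not called in the authors' DESeq2 columns. DESeq2 on the recovered reads of the 6 libraries called both. It put Hbb-bs at 1.12 (DESeq2 adjusted p = 5.28e-10) and Thbs2 at -1.05 (DESeq2 adjusted p = 1.86e-12). The naming rule took 23 genes from the interferon, MHC class I, T and NK, checkpoint and dendritic lists, and in the authors' columns all 23 had smaller changes than here. There 1 of the 23 was called, Itgax at -0.84 (adjusted p = 0.0184), and 2 had no adjusted p. Among those not called were Irf1 at -0.26 (adjusted p = 0.758), Ciita at -0.39 (0.784), B2m at -0.19 (0.574), Cd3d at -0.96 (0.537), Cd8a at -0.50 (0.832), Pdcd1 at -0.40 (0.871), Lag3 at -0.90 (0.317) and H2-Aa at -0.85 (0.436). Of the named genes in other lists, the authors' columns called 4 of 4 for nucleotide synthesis, 4 of 5 for the cell cycle and 3 of 10 for glutamine, all higher. They called 0 of 4 in each of the hypoxia, glycolysis and aminoacyl-tRNA synthetase lists. Over all genes they called 447 of the 11336 with an adjusted p. The naming rule took up to 4 members of smallest p here from each list, so the named genes' shares are not an independent check. Cad and Pfas count in both the nucleotide and the glutamine list. The mean column of the authors' table is not the mean of the 6 libraries: in 1976 gene models with 1 read in 1 library, that library's value was a median of 8.05 times the deposited mean. Which libraries and model the authors' comparison used is not given in the sources used here, so its values and those computed here may not rest on the same samples.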

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

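The tests in this part were chosen after the results they bear on were seen, except the uncorrected list medians without 1 library, which were planned, and the test of ribosomal protein genes against transcript length with all 6 libraries.

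The authors' deposited table gives a mean above 0 to 567 gene models that have no read in any of the 6 libraries, a signal in a column the comparison does not use. The highest such mean is 0.76. Single-read values were a median of 8.05 times the deposited mean, and the deposited mean lay within 1% of the mean of the 6 for 22% of 23228 gene models with a read, so the mean column is not that of the 6 libraries alone. The other comparison columns also differed from DESeq2 on the recovered reads of the 6. Thbs2 stood at -0.68 in the authors' columns against -1.05, and Hbb-bs at 0.62 against 1.12. Of the 483 DESeq2 calls on the recovered reads, 218 were shared. Which libraries or model gave the authors' columns was not tested.

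Of the 10 ways to split the 6 libraries into 3 and 3, the real split gave 5 genes and the highest other gave 0, so 1 split gave as many. For lists the real split gave 17 and the highest other 18, and 4 splits gave as many or more, with 9 to 18 lists in the 9 other splits. With 10 splits the share cannot fall under 0.1.

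The interferon, MHC class I, T and NK, checkpoint and dendritic lists were lower in PEG-glutaminase tumours. PEG-glutaminase 2 alone does not account for all of this: without it the highest of the 5 medians was -0.38, and the other treated libraries still lay below all 3 vehicle libraries in each list. The margin was small in places. PEG-glutaminase 3 lay at 0.28, 0.11 and 0.0352 in the T and NK, checkpoint and MHC class I lists. The lowest vehicle library lay at 0.41, 0.29 and 0.18. In the interferon and dendritic lists PEG-glutaminase 3 lay at -0.0389 and -0.38 against 0.24 and 0.0851. The lists are not independent. An equal fall of leukocytes of every kind is argued against by the macrophage list, whose median exceeded that of the T and NK list by 1.10 (bootstrap interval over genes, not mice, 0.92 to 1.45), and by 0.66 (0.46 to 0.83) without PEG-glutaminase 2. The gap between the 2 list means was 0.49, 1.63 and -0.31 in PEG-glutaminase 1, 2 and 3, and -0.68 to -0.55 in vehicle libraries. As 9 macrophage markers were higher and 15 lower, their median does not show that macrophage content was unchanged. A transcript length trend is argued against too, since after length correction the highest of the 5 medians was -0.67, and -0.35 without PEG-glutaminase 2. An effect of the treatment on lymphoid and dendritic cells or on interferon signalling may underlie it, as may differences in how each tumour was sampled, and with no list passing at an estimated correlation this remains a hypothesis.

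The skin list was lower in PEG-glutaminase tumours, and vehicle 1 held 91.6% of the list's summed normalized counts over the 6 libraries. Skin tissue carried into that sample is a candidate explanation for most of it, with Krt10, Krt14 and Krt1 at 2064, 1727 and 1671 normalized counts there; 1 of the list's 15 tested genes, Perp, is also in the p53 list. Vehicle 3 held 3.47% and each other library 0.974% to 1.4%. The remaining difference without vehicle 1 was not tested against another source.

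Short transcripts, among them 80 ribosomal protein genes with a median of -0.19 (79 lower), were lower in PEG-glutaminase tumours, though vehicle 2 stood apart with 9.74% of reads from ribosomal protein genes against 7.75% and 7.91% in the other vehicle tumours and 7.26% to 7.64% in the treated, and without it the median was -0.07. Over all genes limma called 0 of the 80 (27 unadjusted) and DESeq2 called 12 lower. No list test was run on them. The length trend could account for the oxidative phosphorylation list, whose median went from -0.11 to -0.00114 after correction (interval -0.04 to 0.04). The ribosomal protein genes kept a median of -0.11 (interval -0.16 to -0.06), past the bound set beforehand, but without vehicle 2 the corrected median was -0.0225 (-0.0533 to 0.0224), so that bound overlooked what 1 library can do and the length trend stays open for them. It does not account for the cell cycle, nucleotide and glutamine lists, whose lowest corrected median was 0.14, and 0.0735 without PEG-glutaminase 2. The trend also differed between libraries of a group, so differences in RNA or library quality stay open beside the treatment; labels give no batch to test.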

How the results depend on the processing

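The length correction, the removal of 2 libraries together, edgeR with TMM scaling and TMM and upper quartile scaling within limma were chosen after seeing the data. The 5 genes called were the same 5 with either pseudocount, a mean of at least 50, the stricter filter, both other scalings, edgeR with 3 scalings and limma-voom. With no filter 136 genes passed (25 at least 2-fold), with DESeq2 483 (78 at least 2-fold) and at an adjusted p of 0.1, 9; all of these hold the 5. The cause of the higher counts was not tested. Leaving out 1 library gave 0 to 26 genes, 0 to 15 at least 2-fold and 13 to 19 lists, and the cause was not tested. Without vehicle 1 and PEG-glutaminase 2 together 6 genes passed, 1 of them shared, and after length correction 6, all 5 shared. TMM and upper quartile scaling moved the median of all genes by 0.00463 and -0.00812. Depth limits what low genes can show: most of those with a mean under 10 normalized counts were tested only with no filter (23228 genes tested, against 13557). The list test was not run under DESeq2.

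With the number as a replicate block 1 gene passed (1 at least 2-fold), none of the 5, with 1924 at an unadjusted p under 0.05. Same-numbered libraries had correlations of deviations of -0.13, -0.21 and -0.22, and 0 of 6 correlated best with their own number, so the numbers do not pair the mice. The block left 16 lists past the threshold.

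Lists past the threshold went from 17 to 0 with an estimated correlation and to 1 with fry; the estimate widens the error of lists whose genes move together. Of 415 comparisons of single lists that keep all 6 libraries, 355 kept call and direction, 37 lost and 7 gained the call and 16 turned direction, while of 1296 for named genes 1239 kept both, 5 lost and 52 gained the call.

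Direction turned only in results that did not pass with all 6 libraries, and the cause was not tested. Without vehicle 1 and PEG-glutaminase 2, test directions turned for macrophage (median -0.0356), neutrophil (0.25), fibroblast (0.0127), cholesterol (-0.0141) and immediate early (-0.0520) lists. After length correction they turned for macrophage (-0.00561), neutrophil (0.0134), B cell (-0.0177) and immediate early (-0.0632) lists, and with no filter for macrophage (-0.0579) and B cell (0.21) lists. For neutrophil and B cell lists they turned with upper quartile scaling (-0.0166 and -0.10), edgeR with TMM (-0.0935 and -0.0102), RLE (-0.0985 and -0.0151) and upper quartile (-0.11 and -0.0208), for the neutrophil list with fry (-0.00871) and for the B cell list with a pseudocount of 5 (-0.0699). Leaving out 1 library turned macrophage (-0.16 to 0.0697), neutrophil (-0.27 to 0.26), B cell (-0.31 to 0.27), fibroblast (-0.0461 to 0.23), cholesterol (-0.10 to 0.24), immediate early (-0.20 to 0.0214) and muscle (-1.03 to 0.0373) lists. Of these turned lists, neutrophil passed as higher without PEG-glutaminase 2 and cholesterol as lower without vehicle 2. It also turned Atf4 (-0.10 to 0.0400), Slc7a11 (-0.0944 to 0.0855) and Trib3 (-0.0440 to 0.22).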

Other observations

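The test of the hypothesis in this part was written before the values of its genes were looked at, except that Mrc1 had already entered the macrophage list. The transcripts that prompted the hypothesis were chosen after their values were seen. Several transcripts of tissue macrophages were higher in PEG-glutaminase tumours, none past the limma threshold. The scavenger receptor Stab1 stood at 1.29 ± 0.21, the transglutaminase F13a1 at 2.12 ± 0.37, the chemokine Ccl6 at 1.35 ± 0.26 and the folate receptor Folr2 at 0.99 ± 0.21 (limma adjusted p of 0.113 to 0.129, no overlap between groups in any of the 4). DESeq2 called all 4 higher (DESeq2 adjusted p of 2.01e-10 to 0.000326).

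The hypothesis was that macrophages of the tissue-resident type made up more of these tumours. Of 16 other markers of that type 13 could be tested, 12 were higher, and their median was 0.61, above 100% of 10000 random lists of like expression, whose middle 95% ran from -0.14 to 0.15. Mrc1, the mannose receptor and the most abundant of these markers over all libraries, went from 2283 ± 322 to 6239 ± 2358 normalized counts. In vehicle tumours alone Selenop had a higher mean, 2346. Mrc1 stood at 8955 in PEG-glutaminase 2, which also had the highest muscle, fibroblast and endothelial list means, against 5036 and 4725 in the other treated tumours. Without PEG-glutaminase 2 the median was 0.41, limma called 0 of the 13 over all genes with all libraries (5 unadjusted) where DESeq2 called 4 higher, Mrc1 among them, and 1 of them is also in the macrophage list, which did not pass. A shift in macrophage type may underlie the pattern, and random lists leave out the correlation between markers of a cell type. The markers were also measured in the same tumours as the transcripts that prompted the hypothesis. Their rise is therefore not an independent check of it.

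Cirbp, the other well-known cold-inducible RNA-binding protein, stood at -0.75 ± 0.14 beside Rbm3 (limma adjusted p = 0.111) and was called lower by DESeq2 (DESeq2 adjusted p = 0.000653). Skeletal muscle genes varied within both groups, with Acta1 at 15.4 to 816 normalized counts in PEG-glutaminase tumours, highest in PEG-glutaminase 2, and 104 to 577 in vehicle tumours. The first principal component held 50.7% of the variance and had vehicle 1 and PEG-glutaminase 2 at its opposite ends. The genes weighing most at the vehicle 1 end were skin genes, led by Krt14, Krt1, Lor and Krt5, so the component is not one of treatment alone. It also parted the groups, with vehicle 1, 2 and 3 at -34.0, -2.38 and -6.67. PEG-glutaminase 1, 2 and 3 lay at 12.7, 25.3 and 5.04.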
